A study of Arabidopsis halleri and Arabidopsis lyrata with 12 samples.

How the data were processed

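Small RNA was sequenced from floral buds of 11 plants of Arabidopsis halleri and 1 plant of its relative Arabidopsis lyrata, each labelled with its genotype at the S locus, which controls self-incompatibility in these plants. Per the labels' protocols, total RNA came from 10 to 20 buds per plant, of flower stages 1 to 12, and small RNA of 15 to 40 nt was prepared by the standard SOLiD and PROTON procedures. Which library was run on which of these platforms is not given in the sources used here. Bowtie is named as an aligner per the submitters' processing notes, with no version. The reference that reads were aligned to, the mismatches allowed and any filter are not given in the sources used here.

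Each file the authors deposited lists distinct small RNA sequences of 1 library with a whole-number count each, and neither a position nor a haplotype. The unit was taken from the values, which are whole numbers from 1 upwards, with a different sum in each file. Sequences of 18 to 35 nt are listed, so that the sum of counts describes the listed part of a library and not its sequencing depth. The counts are more often even than odd, so a count is not treated here as a number of separate reads. All values per 1000 are relative to the sum of counts of the same file. No reference genome and no S haplotype sequence was used here.

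Because the files place no sequence on a haplotype, the tests planned on reads per haplotype were replaced by values built from allele sharing, with no test per allele. For each allele carried by at least 2 A. halleri plants (S1, S13, S3, S12 and S20), a plant was left out and a set was formed from the others. The set held the sequences listed by at least 2 other carriers, or by the only other carrier, and by no plant labelled without the allele. The left-out plant was then scored for the share of the set it listed and for its counts per 1000. For S12 and S20 the set that scores a carrier comes from 1 plant and the set that scores a non-carrier from 2 plants, so both values differ in construction. The plant labelled S3-Sx was not used as a non-carrier, since Sx may be any allele, and the A. lyrata plant entered no set. This rule was settled after a first look at such sets.

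Plants were also compared by the share of sequences in common, as a percent of the shorter of the 2 lists. The mean over pairs that share an allele was compared with that over pairs that share none by permuting the genotype labels over 10 plants (100000 permutations, two-sided, S3-Sx left out). That test was chosen after the shared sequences had been counted. Within plants whose alleles both have other carriers, the counts of the 2 alleles were compared as log2(count + 1), with an exact sign-flip permutation test over plants. Each allele's count was the mean, over its other carriers, of the plant's counts of sequences listed by both and by no non-carrier. Agreement between carriers was Spearman's rho and Pearson's r of log2(count + 1) across sequences, which are not independent replicates. Libraries titled BC were compared with the other A. halleri libraries by an exact permutation test, since the title prefix is the only label that might mark a batch. What the prefixes stand for is not given in the sources used here.

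In place of genomic loci, sequences of a library were joined into overlap groups when they shared 16 nt exactly on either strand. Sequences with an N or with at most 6 different 3-nt words were left out. Groups with at least 10 counts were kept, and groups with at least 50% of counts at 20 to 22 nt and at least 80% on 1 strand were counted separately. A group is no proof of 1 locus, because repeats join. Relatives of a leading sequence were searched among sequences with at least 10 counts, over at least 18 nt with at most 3 mismatches, beside 199 shuffled versions of it. The limit was lowered to 3 after shuffled versions had matched too often at a looser limit.

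Sequences are named by a rule set for files without positions: the 10 with the largest summed count, and up to 3 per allele with at least 10 counts in all its carriers and none in plants labelled without it (S3-Sx not counted), ranked by count. Leading sequences of overlap groups and their relatives fall outside that rule and were chosen after their values were seen. Of the lists fixed beforehand, mature sequences of 14 conserved plant microRNA families and of miR867 and miR4239 were searched, in the A. thaliana form, written from general knowledge after the lists of sequences had been seen. None of the 14 conserved sequences was listed in any library, and miR867 and miR4239 were each listed in 1 library. The other conserved families, mir1887, mirS1 to mirS7, the S-locus genes and degradation fragments were not searched, for lack of sequences or names.

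Shares of counts carry 95% exact Clopper-Pearson intervals, which cover counting error only and are too narrow where a read adds more than 1 to a count. Scripts were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, ViennaRNA 2.7.2 (pairing energies) and matplotlib 3.10.9. They were tested on simulated data. For the comparison of plants by sequences in common, 119674 simulated sequences gave a permutation p of 0.0005 with an allele effect (2000 permutations, the smallest they can give) and of 0.781 without. In that simulation, 98.6% of the sequences in left-out sets of S1 and S13 belonged to the allele. Each simulated allele had its own pool of sequences, whereas real haplotypes may have sequences in common, so that share does not carry over to the data. For overlap groups, all 300 simulated loci were recovered, including all 50 of 20 to 22 nt. Those loci were independent random sequences, the 50 with reads from 1 strand only. Real sequences join through repeats, so that recovery does not carry over to the data either. The sample groups, the planned tests, the naming rule and most of the other settings were fixed before the data were examined. The sets built from allele sharing, the label permutation, the overlap groups and the remaining settings came afterwards. Alternatives were other size limits, a minimum count, distinct sequences in place of counts, leading sequences left out, other pseudocounts and group limits, and plants left out 1 at a time. For the folds and the agreement of S12 and S20, no carrier was left out.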

Results

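The series profiled small RNA in floral buds of plants with known genotypes at the S locus, where dominance between alleles is thought to be set by small RNAs that act on the pollen gene of the other haplotype. Each of 12 genotypes was represented by 1 plant, so no value has a replicate check within a genotype, and plants that share an allele were the only replication. In A. halleri, 5 plants carried S1 (with S3, S20, S4, S15 or S12), 4 carried S13 (with S28, S2, S10 or S12), 3 carried S3, and 2 each carried S12 and S20. The A. lyrata plant was labelled S14-S14. Summed counts ran from 51096 (S1-S12) to 133595 (S1-S4) in A. halleri, against 22667 in A. lyrata. The lists held from 2994 distinct sequences (S1-S20) to 25839 (S13-S10). Over all libraries, 100681 distinct sequences were listed, of which 79.1% occurred in 1 library.

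Plants with a common S allele listed many of the same small RNAs, and plants without one listed few. The share of sequences in common was 27.3% ± 7.35 (SD, n = 19 pairs) of the shorter list where an allele was shared and 5.82% ± 3.12 (SD, n = 26 pairs) where none was, a 4.69-fold ratio, over the 10 plants with known alleles. Pairs with S13 in common shared 31.4% ± 8.70 (SD, n = 6 pairs), pairs with S3 27.4% ± 1.96 (SD, n = 3 pairs, including those with S3-Sx) and pairs with S1 25.6% ± 7.0 (SD, n = 10 pairs). The S13 pairs lay between 32.5% and 42.7% within the BC title series, and between 22.7% and 25.6% for S13-S28 against those libraries. The single pairs for S12 and S20 shared 25.2% and 23.6%. By this measure, the lowest pair with a common allele (S1-S3 and S1-S4, 14.2%) lay above the highest pair with none (S13-S28 and S1-S4, 13.4%). As a percent of the sequences listed by either plant, the means were 10.1% and 1.71%, but the ranges overlapped. There, S1-S20 and S1-S15 shared 4.35%, below the 5.31% of S13-S28 and S1-S4. The plant S3-Sx shared 28.9% with S1-S3 and 28.1% with S3-S20, and between 1.64% and 6.43% with A. halleri plants lacking S3. Permuting genotype labels over the same 10 plants gave p = 3e-05 for the difference of 21.5 percentage points (permutation test, two-sided). Pairs from the same title series all shared an allele, and between series the shares were 24.2% ± 5.88 (SD, n = 10 pairs) and 5.82% (permutation p = 3e-05).

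**Figure D1:**
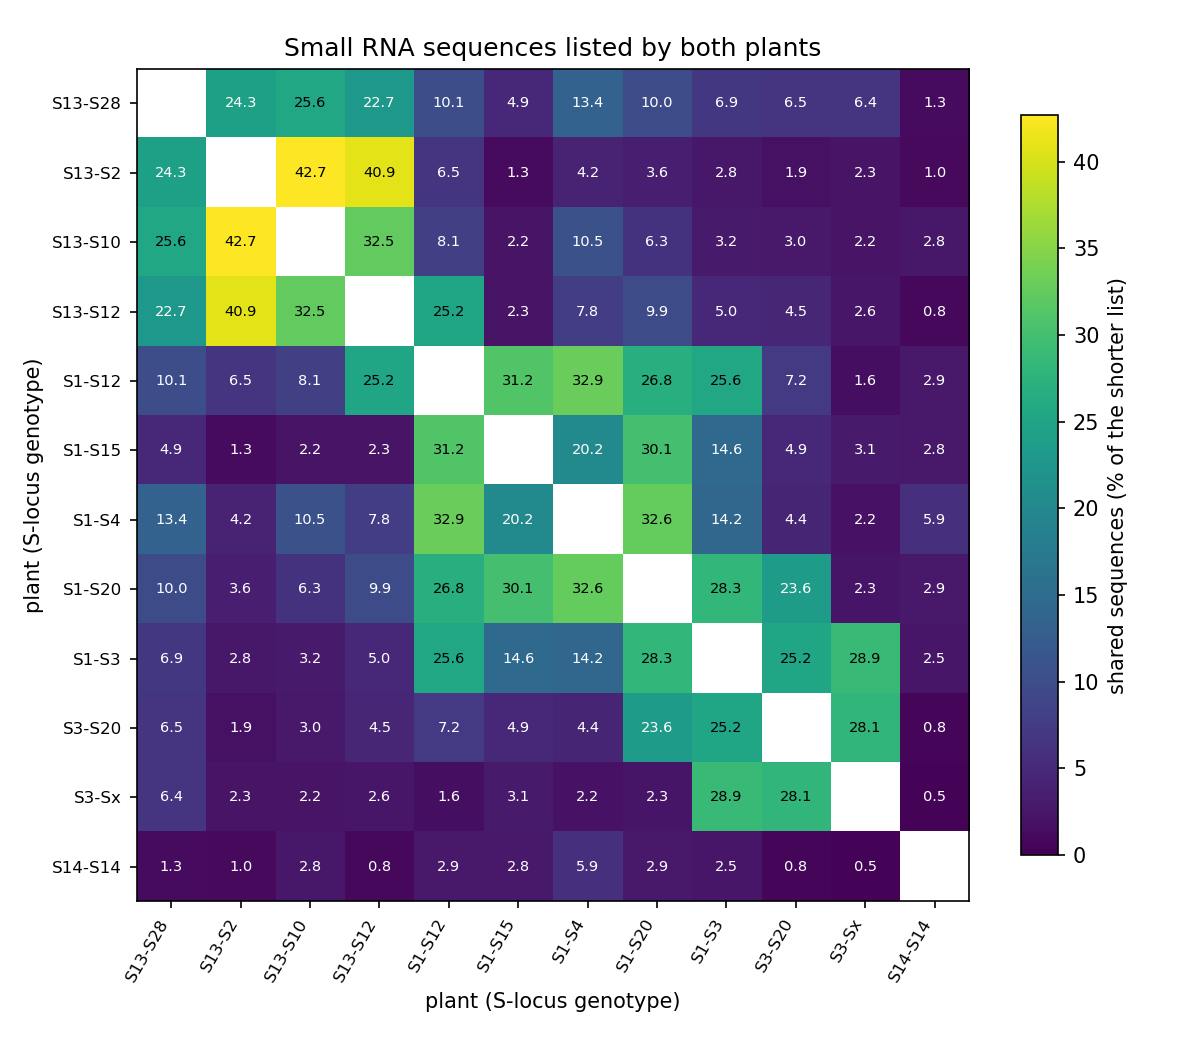
Percent of the shorter list that both plants of a pair listed, for each pair of the 12 plants (rows and columns, by S-locus genotype, ordered by allele). Pairs with a common allele lie between 14.2% and 42.7%, and A. halleri pairs with known alleles and none in common between 1.31% and 13.4%.

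For S1, S13 and S3, a left-out carrier listed a large part of the set of sequences from at least 2 other carriers and no non-carrier. Plants without the allele listed few of their sets, from which all sequences of the other non-carriers had been removed, which can lower their shares. Of the S3 set, left-out carriers listed 56.6% ± 3.73 (SD, n = 3) and non-carriers 0.994% ± 1.5 (SD, n = 8). For S13 these shares were 51.8% ± 14.3 (SD, n = 4) and 1.47% ± 1.44 (SD, n = 6), and for S1 45.8% ± 12.2 (SD, n = 5) and 4.81% ± 3.34 (SD, n = 5). The S13 mean combines 57.5 to 61.3% in the 3 BC-titled libraries with 30.4% in S13-S28, the only carrier from another title series. For S12 and S20 most of the set did not return, but a carrier's set there came from 1 list and kept its private sequences. The S1-S12 plant was scored on 9530 sequences from S13-S12, a library with 9022 sequences listed nowhere else. Non-carriers were scored on sequences that both carriers listed, so the shares of carriers and non-carriers differ in construction. The S12 carriers listed 26.3% (S13-S12) and 5.15% (S1-S12) of their sets, against at most 4.66% in non-carriers, and the S20 carriers 25.2% (S3-S20) and 6.26% (S1-S20), against at most 5.17%. As counts per 1000, the S1 set reached 203 ± 70.5 in carriers and 15.1 ± 13 in non-carriers, the S13 set 341 ± 128 and 30.5 ± 36.6, and the S3 set 215 ± 42.1 and 5.42 ± 11.5 (SD, same n). The fold was 13.5 for S1, 11.2 for S13 and 39.7 for S3. For S12 the mean was 72.7 ± 43.8 per 1000 (SD, n = 2) against 0.905 ± 0.859 (SD, n = 8), and for S20 168 ± 78.5 (SD, n = 2) against 0.797 ± 0.722 (SD, n = 8), folds of 80.4 and 211. The S12 and S20 folds compare sets of unlike construction, so they cannot be ranked with those of S1, S13 and S3. For S3, too, carriers were scored on 1478 to 1683 sequences and non-carriers on 2933 to 3064. The S1, S13 and S3 folds also differ in the numbers of carriers that form a set and of non-carriers that clear it. They are therefore not ranked among themselves either. No test was run on these values, because the sets were defined by the labels. The highest non-carriers of the S13 set were S1-S12 with 88.1 and S1-S4 with 65.3 per 1000. The S1 fold was 2.40 without the BC-titled libraries, which left S13-S28 and S3-S20 as its non-carriers, and other settings moved the S3, S12 and S20 folds to values between 18.6 and 644. Single plants moved the folds by over 1.5 times, though none to below 5.30. The S1 fold was 23.1 without S1-S4, 21.9 without S1-S15, 5.30 without S3-S20, 6.33 without S13-S28, 7.04 without S13-S12 and 7.19 without S13-S10. The S13 fold was 16.8 without S13-S28, 6.30 without S13-S2, 19.5 without S1-S12 and 7.44 without S1-S15. For S3, S13-S28 held 33.3 per 1000 and the other non-carriers at most 6.59, and the fold was 114 without S13-S28. It was 65.8 without S3-S20 and 69.1 without S1-S3, where the sets also rest on 1 other carrier in place of 2. The S12 fold was 27.7 without S3-S20, 35.8 without S1-S20 and 50.2 without S13-S10, and the S20 fold 53.2 without S13-S12, 68.2 without S1-S4, 79.4 without S13-S28 and 95 without S1-S12.

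The sequences listed by all carriers of an allele and by no non-carrier were mostly of 24 nt, the size of siRNAs that guide DNA methylation in plants. As distinct sequences, the 24-nt share ran from 56.4% (S20) to 78.5% (S3). There were 1491 such sequences for S13, 883 for S3, 491 for S12, 367 for S20 and 285 for S1. These numbers depend on how many carriers must all list a sequence and on the lengths of their lists, so they do not rank the alleles. By counts, the 24-nt share was 82.3% for S13, 84.5% for S3, 84.1% for S12 and 80.8% for S1, against 47.3% for S20. For S20, 46.0% of the counts were of 20 to 22 nt, the size range of microRNAs. Most of that came from ACAAGTTGCAGCATAACACGT, a 21-nt sequence listed in both S20 plants and in no other plant. It had 5230 counts in S3-S20 and 4917 in S1-S20, or 60.2 ± 22.1 per 1000 (SD, n = 2). The sequence made up 51.1% of the 21-nt counts of S3-S20 and 63.4% of those of S1-S20. The 24-nt sequence AACACGTAAACACATAAACACACT was also restricted to the S20 plants, at 9.72 and 29.9 per 1000.

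The named sequences of the other alleles, of 23 or 24 nt, stood at lower levels. In S3 carriers, AAAGCTTTTGTGATTGGTAACTGT stood at 9.18 ± 5.30 per 1000 (SD, n = 3) and ACCGCGTTGTATAAAACAGATGGG at 5.17 ± 1.95 (SD, n = 3), both without a count in other plants. In S1 carriers, GACCCTTATTAGATCCACGACAGA stood at 7.92 ± 6.13 per 1000 (SD, n = 5), ACCAAACATTTGCATTGAAAACCT at 7.68 ± 6.15 (SD, n = 5) and the 23-nt CAACTCAAAACCAATTGGCAATG at 5.69 ± 3.46 (SD, n = 5). In S13 carriers, AGAGCAAACTCGTGCTGATAACGT stood at 4.63 ± 2.92 per 1000 (SD, n = 4) and AATGCCACTTTTCAAAAATACCCC at 3.21 ± 2.47 (SD, n = 4). The S12 carriers shared ACAGTTGACCGAAAAGATAAGTGC at 1.45 ± 0.225 per 1000 (SD, n = 2) and its exact complement GCACTTATCTTTTCGGTCAACTGT at 0.989 ± 0.207 (SD, n = 2). Sequences with at least 10 counts in all carriers and none in plants labelled without the allele numbered 296 for S3, 156 for S13, 110 for S20, 93 for S1 and 46 for S12. Of those for S13, 1 was also listed in S3-Sx. The numbers per allele depend here too on how many carriers there are and on the lengths of their lists.

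Several of the sequences with the largest summed counts crossed allele boundaries. GTGGAACAAACCTAAAACACTAGA, with the largest count summed over all libraries (10841), was listed in the 3 S3 carriers at 18, 27.5 and 53.8 per 1000, and also in S13-S28 at 5.64 per 1000. AACGGTATACCACGAGTCCACGAG occurred in all 5 S1 carriers, at 33.2 per 1000 in S1-S20 and 35.2 in S1-S12 but between 4.13 and 10.1 in the others, and also in S3-S20 and S13-S12. The sequences AACCCAACTCATACACCGGATATT and ATATTTAACCCAACTCATACACCG were listed in the same 7 plants. TCCGTTATTTCCACATGCTCC, of 21 nt, had 5666 counts in S1-S4, 44.9% of the 21-nt counts of that plant, and 430 in S13-S10. GAACCAATAGTAATCTAAAACAGT was the most widespread of the 10, with 8 plants.

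**Figure D2:**
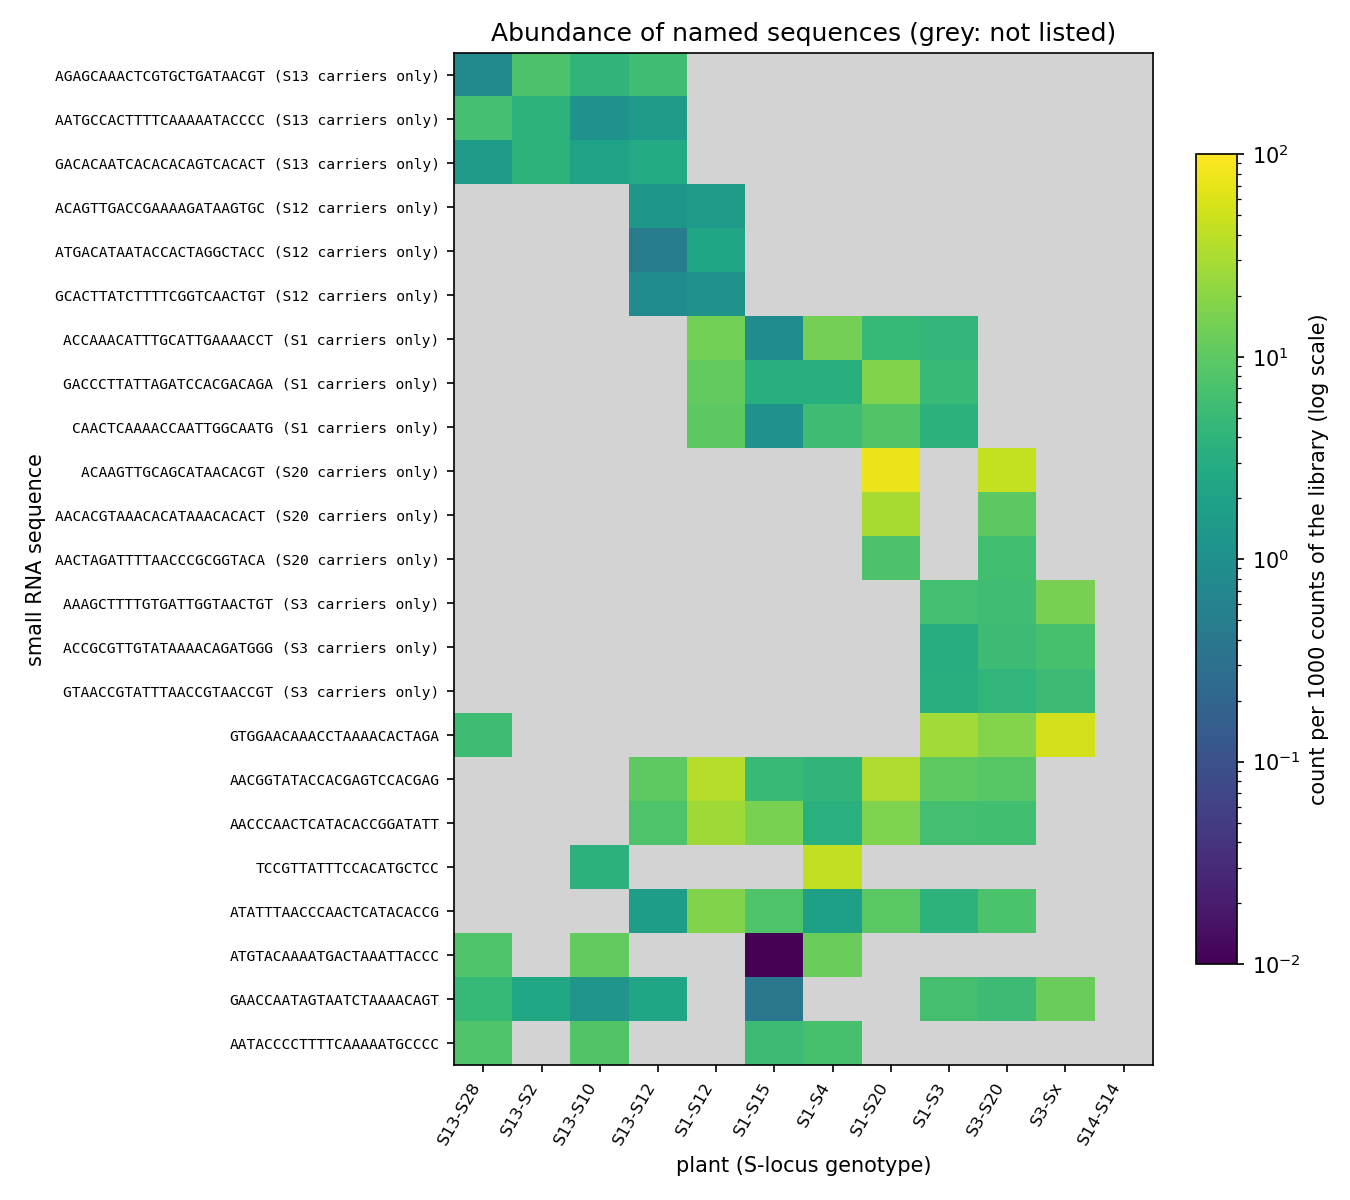
Counts per 1000 counts of the library (log scale) for each named sequence (rows) in each of the 12 plants (columns, by S-locus genotype); grey marks a sequence not listed. Rows marked with an allele were listed in all its carriers and no other plant, led by the 21-nt S20 sequence at 44.6 and 75.9 per 1000.

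Within heterozygous plants, the counts of sequences in common with other carriers of each allele were compared, and no constant direction relative to S1 was found. In S1-S3, sequences shared with other S3 plants had 28465 counts and those shared with other S1 plants 17163, a log2 difference (partner minus S1) of 0.73. In S1-S20 the partner had 14476 and S1 16042 (-0.15), and in S1-S12 the partner had 5300 and S1 13818 (-1.38). The mean was -0.27 (SD 1.06, n = 3), with an exact sign-flip p of 0.75, where 3 plants cannot go below 0.25. In S13-S12, the S12 sequences had 3569 counts and the S13 sequences 29268, a log2 difference of -3.04 in 1 plant. Each allele's value depends on the lists of its other carriers, which for S12 in S13-S12 was 1 list of 3952 sequences and for S13 lists of 13983 to 25839, so these values are not haplotype outputs. The S1 mean turned to 0.28 without S1-S12 and to 0.50 with 21 to 22 nt alone.

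Small RNA of 24 nt dominated the listed counts of every library. None of the 14 conserved microRNAs searched was listed, so these size shares describe the lists and not the whole small RNA of a plant. It made up 65.9% ± 3.20 (SD, n = 11) of the counts in A. halleri, from 60.9% in S1-S4 (95% exact Clopper-Pearson interval 60.6 to 61.1%) to 69.8% in S1-S12 (69.4 to 70.2%), and 55.9% (55.3 to 56.6%) in A. lyrata. The 23-nt class held 14.4% ± 0.920 (SD, n = 11). The 20- to 22-nt class held 15.3% ± 2.53 (SD, n = 11), lowest in S1-S12 (11.7%) and highest in S1-S20 (19.1%), with 18.8% in A. lyrata. Within it, 22-nt sequences were above 21-nt sequences in 8 of 11 A. halleri libraries, most in S1-S15 with 11.5% of all counts at 22 nt and 4.56% at 21 nt, while 21-nt sequences led in S1-S20 (12.0%), S1-S4 (9.44%) and S3-S20 (8.72%). Among distinct 24-nt sequences, 47.6% ± 1.30 (SD, n = 11) began with A and 12.2% ± 3.16 (SD, n = 11) with T. Counted as distinct sequences, the 24-nt class held 51.9% and the 20- to 22-nt class 21.9%. Genotypes were not tested against each other, with 1 plant each.

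**Figure D3:**
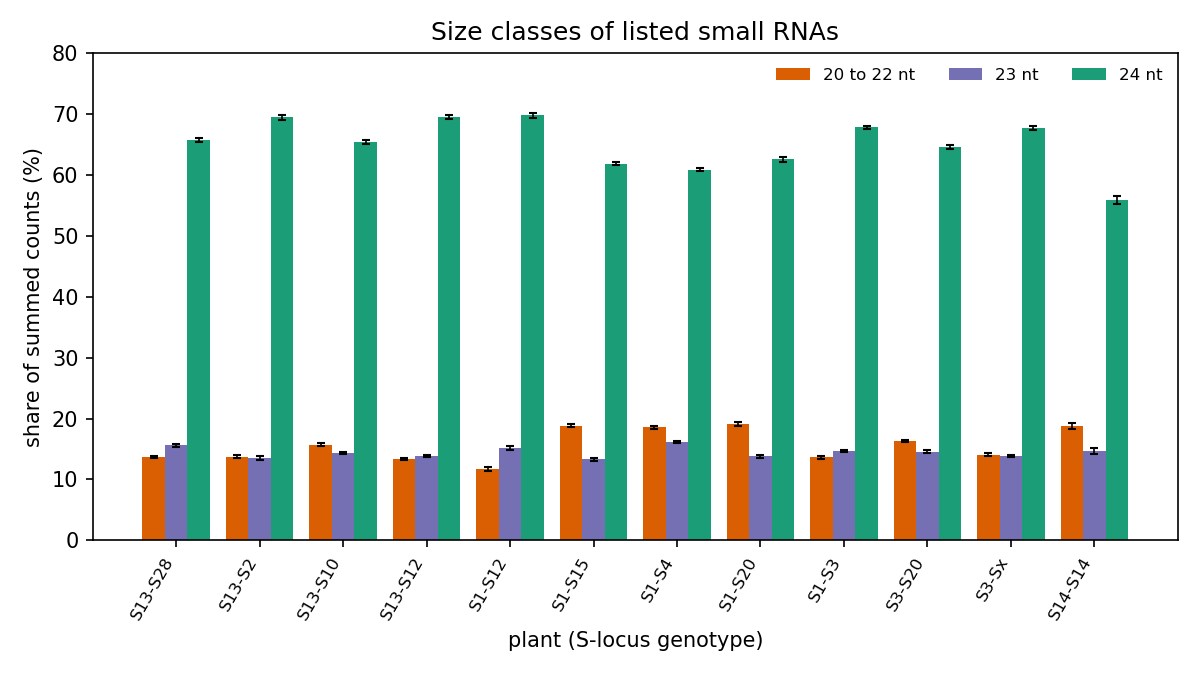
Share of summed counts (percent, vertical axis) at 20 to 22 nt, 23 nt and 24 nt in each of the 12 plants (horizontal axis, by S-locus genotype), with 95% exact Clopper-Pearson intervals that cover counting error only. The 24-nt class lies between 55.9% and 69.8% of the listed counts in every library.

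The 3 libraries titled BC, all from S13 carriers, did not differ past the test in their small size classes. Their 20- to 22-nt share was 14.3% ± 1.25 (SD, n = 3) against 15.7% ± 2.83 (SD, n = 8), a difference of -1.47 percentage points (exact permutation p = 0.4, two-sided, smallest possible 0.0121). It was 0.242 points as distinct sequences and -4.78 points with at least 10 counts (exact permutation p = 0.0606). In a comparison added after the lists had been seen, they held more sequences with a count of 1, which made up 44.0% ± 0.867 (SD, n = 3) of their lists against 17.6% ± 8.74 (SD, n = 8; exact permutation p = 0.0121). The S13 carrier outside that title series, S13-S28, had 28.1%.

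Groups of microRNA-like size and strand held a small part of the listed small RNA, between 0.352% (S1-S12) and 9.27% (S1-S20) of the counts. Over the 12 libraries, 367 groups were mainly of 20 to 22 nt and from 1 strand, between 4 (S13-S2) and 83 (S3-Sx) per library, and 28 of these had at least 100 counts. The group of ACAAGTTGCAGCATAACACGT held 7127 counts in S3-S20 and 5181 in S1-S20, and 73.4% and 94.9% of them were that single sequence. The group of TCCGTTATTTCCACATGCTCC held 8092 counts in S1-S4, 70.0% of them that sequence. Smaller groups were led by TTGCAAGTAACCGATCAAAAC in both S20 plants (137 and 83 counts) and by TCTCCACTAAGATGATACATA in the S3 carriers (42, 204 and 172 counts). The S3-Sx plant alone had a group led by AACAACCAATGGTTTCAGATT, with 400 of 402 counts. The number of groups depends on the minimum count, with 43 at 50 counts and 948 at 3 counts.

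Of the microRNA families linked to the S locus, miR4239 and miR867 appeared in S1-S4, and, within 3 mismatches, a relative of miR867 in S13-S10. The A. thaliana form of miR4239, TTTGTTATTTTCGCATGCTCC, had 78 counts in S1-S4 and was listed nowhere else. The miR867 sequence TTGAACATGGTTTATTAGGAA had 4 counts in S1-S4, where its longer form TTGAACATGGTTTATTAGGAAAGA had 212, and S13-S10 had the related TTGAACATGGCTTATAAGGAA with 67. The leading 21-nt sequence of S1-S4, with 5666 counts there and 430 in S13-S10, matches the miR4239 form at most positions, end to end. Its mismatches exceed the limit of 3, so it was not counted as a relative. Whether it belongs to that family was not tested. None of the 14 conserved microRNAs searched was listed in any library.

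Abundances of an allele's sequences were moderately correlated between its carriers. Across sequences listed by both plants and by no non-carrier, Spearman's rho averaged 0.481 for S1 (10 pairs, Pearson's r 0.558), 0.435 for S13 (6 pairs, r 0.565) and 0.436 for S3 (3 pairs, r 0.510). It was 0.233 for S12 (r 0.302) and 0.323 for S20 (r 0.476), with 1 pair each. Among S13 carriers, rho lay between 0.504 and 0.529 for pairs of BC-titled libraries and between 0.331 and 0.369 for S13-S28 against them. Summed over overlap groups in place of single sequences, mean rho was between 0.688 (S20) and 0.818 (S13). These groups hold only sequences listed by both plants, so the number of members is the same in both and can raise rho by itself. With at least 10 counts in either plant, mean rho was between -0.137 (S12) and 0.272 (S1).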

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

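The sets of values tested here were chosen after the libraries had been seen. Carriers of S1 (5 plants) and of S13 (4 plants) were searched for a plant far from the others in 36 sets of values, of which chance alone would pick out about 1 in 20, and 5 values stood apart. In S13 carriers, S13-S28 differed on 3 measures. Sequences with a count of 1 made up 28.1% of its list, against 43.3 to 45.0% in the other carriers. Sequences whose exact complement was also listed made up 19.6%, against 25.1 to 25.6%. It listed 30.4% of the left-out S13 set, against 57.5 to 61.3%. This plant is the only S13 carrier outside the BC title series. The 20- to 22-nt share of S13-S10 was 15.7%, against 13.4 to 13.8% in the other S13 carriers. Among S1 carriers, 34.6% of the sequences of S1-S15 had a count of 1, against 10.7 to 14.3% in the others.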

How the results depend on the processing

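Alternatives for sequences in common, the overlap lengths of 14 and 18 nt, and leaving out non-carriers were chosen after seeing the data. Not run, for lack of positions: only sequences placed on 1 haplotype or at 1 position, counts divided by the number of places, and other gaps between loci. Leaving out the BC-titled libraries gave no value for S13 and S12, which then have 1 carrier each.

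Of 162 alternatives, 103 kept their result, by a rule that differed between results. Folds were kept when they moved by less than the SD of the carriers' log2 values. The S1 partner difference was kept when its sign and its side of the 0.05 threshold held. Its sign-flip p cannot fall below 0.25 with 3 plants, so only a turn of sign could change that label, and 10 of its alternatives were kept. The difference in sequences in common kept its direction and its side of the threshold in all 18, between 19.1 and 23.3 with each plant left out. Its p was 5e-05 (the smallest that 20000 permutations can give) for 24 nt alone, and 0.0022 without the BC-titled libraries, the highest of all.

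Folds of carriers over non-carriers stayed above 1. With at least 10 counts they were 9.56 (S1), 22.5 (S3) and 35.7 (S12). Without the BC-titled libraries they were 2.40 (S1), 18.6 (S3) and 34.7 (S20), with fewer non-carriers to clear the sets. With 21 to 22 nt alone they were 66.5 (S3) and 644 (S20), and as distinct sequences 49.0 (S3) and 107 (S20). With plants left out 1 at a time they ran from 5.30 to 23.1 (S1), 6.30 to 19.5 (S13), 31.1 to 114 (S3), 27.7 to 91.4 (S12) and 53.2 to 228 (S20). For S12 and S20 only non-carriers were left out. For S3 the folds with a carrier left out, 56.2 to 69.1, also change the sets to 1 other carrier in place of 2.

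The mean log2 difference of partners to S1 turned to 0.50 with 21 to 22 nt alone, and ran from -0.77 to 0.28 with each S1 carrier left out, positive without S1-S12. For S13-S12 it was -4.49 (21 to 22 nt), -2.83 (24 nt), -3.42 (at least 10 counts) and -3.15 (distinct sequences), and -3.13 to -2.89 with each other carrier left out.

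As distinct sequences, the 24-nt share was 51.9% and the 20- to 22-nt share 21.9%; with at least 10 counts they were 72.8% and 12.0%. The BC difference turned to 0.242 as distinct sequences (exact permutation p = 0.885), was -4.78 with at least 10 counts (exact permutation p = 0.0606), and ran from -2.18 to -1.01 with each BC-titled library left out. Groups of 20 to 22 nt numbered 43 at 50 counts and 948 at 3 counts.

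Mean rho between carriers with at least 10 counts was 0.272 (S1), 0.115 (S13), 0.179 (S3), -0.137 (S12) and 0.162 (S20), a filter that removes sequences low in both plants. Summed over overlap groups, with the same members in both plants, it was 0.758 (S1), 0.818 (S13), 0.747 (S3), 0.749 (S12) and 0.688 (S20). With each carrier left out it ran from 0.468 to 0.507 (S1), 0.401 to 0.520 (S13) and 0.420 to 0.461 (S3). Causes were not tested otherwise. The short lists, such as S1-S20 with 2994 sequences, limit which shared sequences can be seen.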

Other observations

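Sequences near the leading S20 sequence were listed in plants with other alleles. With at most 3 mismatches to ACAAGTTGCAGCATAACACGT, all 4 S13 carriers listed a relative at 2 mismatches, with between 25 counts (S13-S10) and 528 counts (S13-S28) in all such sequences. They included ACTTGCAACATAACACGTA, CAACTTGCAACATAACACGTA and ACTTGCAACATAACACGTAAA, none of which was listed in any plant without S13. S1-S15 listed ACAGCTTGCAGCATAGCACGTA with 210 counts, at 3 mismatches. Of the shuffled versions of the S20 sequence, 0 had a match at 2 mismatches and 3 at 3 mismatches. The leading sequence of S1-S4, TCCGTTATTTCCACATGCTCC, had a relative at 3 mismatches, GTATCCGTTTTTGCCGCATGCTC, in the other S1 carriers S1-S15 (234 counts), S1-S3 (67), S1-S12 (31) and S1-S20 (12), and 5 of its shuffled versions had a match that close.

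The A. lyrata plant S14-S14 had little in common with A. halleri, but no A. halleri plant was labelled with S14. Its pairs with A. halleri plants of known alleles shared between 0.766% and 5.86% of the shorter list. A. halleri pairs without a common allele shared between 1.31% and 13.4%, so species and allele cannot be told apart. Of the sequences of S14-S14, 9.94% were listed in any A. halleri plant, most of them shared with S1-S4 (237 sequences, with 18.9% of the A. lyrata counts). Its leading sequence AGACCACACTGTGATCCGACTAGC, of 24 nt, had 1809 counts, or 79.8 per 1000, and was listed in 0 A. halleri libraries. The 21-nt GAAGCTAATATATTACCTTGA had 514 counts and was listed in 2 of them.

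Of the tests below, those of the even share by occurrence, of groups with even counts, and of lists of equal length were chosen before their results were seen, and the others after. Among sequences with at least 20 counts, even counts made up between 56.1% (S1-S15) and 79.0% (S1-S4) in A. halleri. The homozygous S14-S14 also had an excess, at 64.3% (exact Clopper-Pearson interval 56.2 to 71.8%), which argues against heterozygous plants as the only source. That interval takes 154 sequences of 1 plant as independent and is too narrow where evenness goes by overlap group. A candidate explanation is that regions present in several copies had each read counted at every copy: where all high counts of an overlap group were even, low counts of that group were even in 85.5% ± 6.67 (SD, n = 11), against 62.2% ± 6.28 in other groups. The median difference was 21.9 percentage points, above 0 in 11 of 11 libraries (exact sign-flip permutation p = 0.000977). Counting at places on other haplotypes predicted a higher even share for sequences also listed in plants without a common allele, and the median difference was -9.32 points; that test cannot exclude counting per alignment place, since a sequence of 1 plant may repeat within its own haplotypes.

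Sharing of sequences by plants with a common allele may reflect small RNA made by that haplotype, or how the lists were made. A common title series as the only source is argued against by pairs from different series, where the difference was 18.3 percentage points (permutation p = 3e-05). Whether title series are batches is not known, and the sequencing platform could not be tested. Unequal list lengths are argued against by lists limited to their 2500 most abundant sequences, where it was 17.3 points. That each library was aligned only to its own plant's haplotypes cannot be told apart from allele-specific production, because the reference is unknown: of the conserved microRNAs searched, 0 were listed, so at least these sequences from elsewhere in the genome are missing from the lists. Such an alignment would hide a small RNA in a plant without its haplotype, and keeps the scarcity in non-carriers open.

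The lead of 1 sequence of 21 nt in the S20 and S4 libraries may be that of a microRNA, or of counting at several alignment places. The number of places must divide a sequence's count and cannot exceed the lowest count of a sequence contained in it, if alignment was exact. Divided by the largest such number, the count was still 2.29 times that of the next sequence in S1-S20 and 1.47 times in S1-S4, which argues against that explanation there, and 0.495 times in S3-S20, where it stays open. A partner strand that pairs with the sequence was sought among listed sequences of 20 to 22 nt: TGGAGCATACGGCAATAACGA in S1-S4 paired at -20.3 kcal per mol (permutation p = 0.03 against shuffled versions). No such partner stood out for the S20 sequence (permutation p = 0.715 in S1-S20 and 0.745 in S3-S20), so that a microRNA-like duplex stays a hypothesis.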
